A study of Xenopus laevis with 4 samples.

How the data were processed

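RNA was sequenced from animal cap explants of Xenopus laevis, the prospective ectoderm cut from a blastula and cultured alone. Per the labels, the explants came from embryos injected at early cleavage stages with synthetic RNA encoding pitx1 or with nuclease-free water, and were harvested at mid-neurula stages. The series holds 4 samples, 2 with pitx1 RNA and 2 with water, sequenced on an Illumina HiSeq2500. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here.

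The deposited material is 1 table of 51177 features, each named only by a Xelaev identifier. Its headers name 4 numbered libraries in groups called Group13 and Group24. No title, description or characteristic of the samples holds these group names, and nothing states which sample a library number stands for. No library could therefore be matched to pitx1 RNA or water without relying on the order of the samples, which was not done. The 24 columns of values per library and the 6 columns of group means were therefore not used here, and the depth of each sample was not analysed. The features were looked up in the reference gene table of assembly Xenopus_laevis_v10.1, and 0 of the 51177 identifiers matched, so no gene could be named. The 27 gene lists, with 816 symbols, that had been fixed before the data were examined (cement gland, hatching gland, placodes, lens, pituitary, neural crest, neural plate, epidermal cell types, mesoderm, endoderm, signalling pathways, stress and others) could not be matched to any feature and gave no result. The planned edgeR model of pitx1 RNA against water was not fitted because its groups could not be assigned.

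What was used are the columns of the authors' own comparison and the gene length. Per the file headers, the deposited table gives for each feature the difference and the fold change between the means of the groups on the original scale, which is RPKM, and after a normalization that the headers do not name. The deposited differences are Group24 minus Group13. The differences of the normalized values summed to 0 over all features. Per the file headers, the authors then compared transformed values with a t-test, whose difference, test statistic, p-value and FDR-corrected p-value were deposited as scores per feature. The transformed values were read as log2 of the normalized values without a pseudocount. The values per library that would show this were not used. On this reading, a feature at 0 in any library on that scale has no test and carries a spreadsheet error instead of a number. The deposited p-value equals the two-sided p of the deposited statistic with 1 degree of freedom in every feature, with a largest gap of 1.7e-13. An unpaired test of 4 libraries has more than 1 degree of freedom in general, and a paired test of 2 pairs has 1, so the test was read as a paired one. The deposited FDR equals a Benjamini-Hochberg adjustment over all 51177 features, untested ones included, with a largest gap of 3.7e-13.

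From these columns the standard error of each log2 difference was computed as the difference divided by the test statistic. The mean RPKM of a feature over both groups was computed from its difference and its fold change. Features were counted by direction, by p-value and by class of mean RPKM and of gene length. Added after the data were seen, the standard errors were moderated across features with limma 3.58.1 (squeezeVar, with a trend on the mean normalized value) in R 4.3.3, and Benjamini-Hochberg adjusted. This step was tested on simulated pair differences with 200 changed features and errors independent between features. With the spread drawn from the fitted prior, 5 of 54 calls among 29198 features were false. With the spread set to the moderated spread of the real features, 62 of 192 calls were false. Other steps used Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

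The rule for named genes asked for gene symbols and an adjusted p under 0.05, which no feature met. The 4 features named are the 2 with the largest log2 difference in each direction among those with an unadjusted p under 0.05, and this substitute was chosen after the data were seen. Nothing in the labels says whether the samples of a group came from separate cultures or clutches, so the spread behind every p-value may be technical.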

Results

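Pitx1 is a homeodomain transcription factor, and the series was made to find genes that respond to it in Xenopus laevis ectoderm. Animal cap explants injected with pitx1 RNA (2 samples) were set against explants injected with water (2 samples) at mid-neurula stages. The deposited comparison is between libraries called Group13 and Group24, and the labels used here do not say which of these received pitx1 RNA. All directions below are therefore given by the table's own group names and say nothing of induction or repression by Pitx1. No feature could be given a gene name, so pitx1 itself and the markers of ectodermal cell types were not examined.

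Of 51177 features in the authors' deposited table, 29198 (57.1%) had a log2 difference and a test. The other 21979 had none. Among these, 9905 had the same RPKM in every library and 12074 varied. Of the 12074, 6236 had a difference but no number for the RPKM fold change. They were read as a mean of 0 in 1 group and above 0 in the other. Group13 was read as 0 in 2669 of them and Group24 in 3567. Nearly all were at low levels. Group24 was at 1 RPKM or more in 7 of the features with Group13 at 0, and Group13 was at 1 RPKM or more in 54 of the features with Group24 at 0. The highest level among the former was 2.75 RPKM and among the latter 36.1 RPKM. These levels are the authors' deposited differences between group means, without an error.

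The authors' deposited test of Group13 against Group24 left no feature under an FDR of 0.05: the count was 0 and the lowest FDR was 0.577. At an unadjusted p under 0.05 it had 2430 features (8.32% of those tested, where chance alone gives 5%), of which 1108 were higher in Group24 and 1322 higher in Group13. On the RPKM scale the same 2430 features divided into 926 higher in Group24 and 1504 higher in Group13. A p under 0.01 was given to 515 features, 220 higher in Group24 and 295 higher in Group13. The low p-values went with at least a 2-fold difference in 1099 features, 508 higher in Group24 and 591 higher in Group13. Whatever the p, 7943 tested features differed at least 2-fold on the log2 scale, and these leaned the other way, with 4487 higher in Group24 and 3456 higher in Group13. They were not divided by abundance. Of all tested features below 0.3 RPKM, 59.4% were higher in Group24 on the log2 scale but 38.6% in RPKM. Above 100 RPKM the log2 share was 32.8%. Adjustment over the 29198 tested features alone left the lowest adjusted p at 0.329 and the count at 0, and a moderated test in limma, computed from the same columns, had 429 over every level, 1447 over a normalized value of 1 and 134 over 5.

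**Figure D1:**
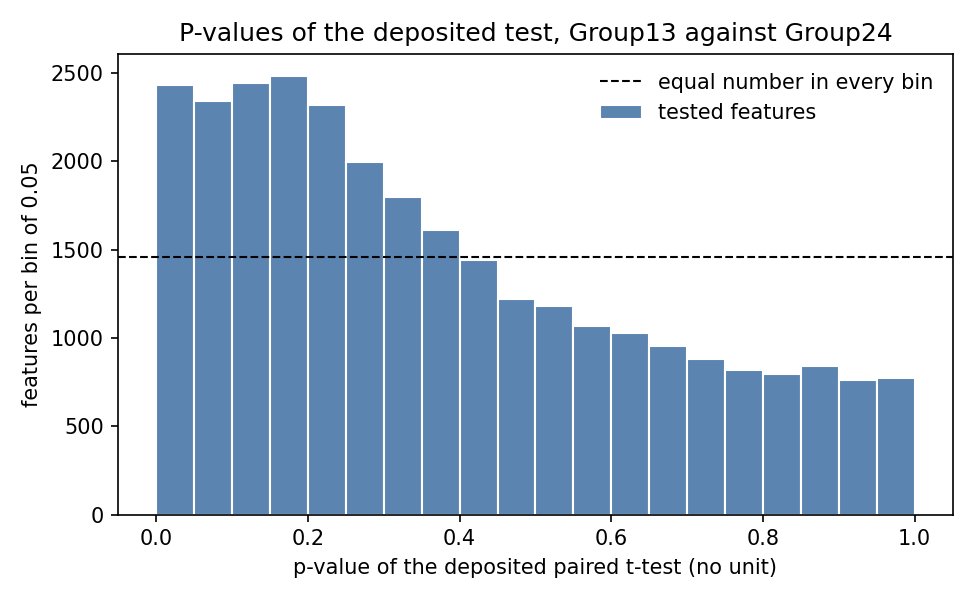
Number of tested features (vertical axis) per bin of 0.05 of the p-value of the authors' deposited t-test between Group13 and Group24 (horizontal axis); the dashed line is an equal number in every bin. The bin under 0.05 holds 2430 features and the bin over 0.95 holds 774, against 1460 expected per bin. The bins from 0.1 to 0.15 and from 0.15 to 0.2 hold 2442 and 2484, so the excess is not particular to p under 0.05.

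Differences were measured with little precision. The median absolute log2 difference in the authors' deposited table was 0.49 and the median standard error, computed from the deposited statistic, was 0.28. With 1 degree of freedom the 95% interval extends 12.7 standard errors to each side, a median of 3.58 log2 units. In the simulated data, no changed feature passed an adjusted p of 0.05 in this unmoderated test, not even the 50 changed by 6 log2 units. Precision rose with abundance. The median standard error was 0.58 log2 units among 4668 features below 0.3 RPKM, 0.31 among 5413 features between 1 and 3 RPKM, and 0.13 among 839 features above 100 RPKM. The median absolute log2 difference fell as well, from 0.79 below 0.3 RPKM to 0.24 above 100 RPKM. The share with a deposited p under 0.05 did not rise, at 8.27% and 7.27% in these classes.

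The largest log2 differences with an unadjusted p under 0.05 were toward Group13. Feature Xelaev15069504m, 2202 bases long, was lower in Group24 by a log2 difference of -9.82 in the authors' deposited table (deposited p = 0.0194), with a computed standard error of 0.30. Its mean was 22.7 RPKM in Group13 and 0.0098 RPKM in Group24. Feature Xelaev15022482m, 605 bases long, had a log2 difference of -9.46 in the authors' deposited table (deposited p = 0.0211), a computed standard error of 0.31, and means of 65.7 RPKM in Group13 and 0.074 RPKM in Group24. The largest differences toward Group24 were in features of low level. Xelaev15017905m, 3635 bases long, had a log2 difference of 6.45 in the authors' deposited table (deposited p = 0.0462), a computed standard error of 0.47, and means of 0.92 RPKM in Group24 and 0.020 RPKM in Group13. Xelaev15023741m, 1985 bases long, had a log2 difference of 5.93 in the authors' deposited table (deposited p = 0.0182), a computed standard error of 0.17, and means of 0.66 RPKM in Group24 and 0.025 RPKM in Group13. None of these 4 features passed the deposited FDR of 0.05. In the limma-moderated test over every level all 4 were under it, at adjusted p-values of 0.0388 for Xelaev15017905m, 0.0419 for Xelaev15023741m and 0.0138 for both features toward Group13. The features were picked by their difference and p-value, and the moderated test reuses the same columns. Their passing is therefore no separate support. The features toward Group24 fell below the minimum normalized values of 1 and 5 and were not tested there. The size of each difference depends on a group mean close to 0.

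The share of features higher in Group24 depended on the normalization. On the RPKM scale 32.3% of the tested features were higher in Group24, with a median log2 ratio of -0.28. On the authors' log2 scale 47.0% were higher in Group24, with a median difference of -0.04. The sign differed between these scales in 4397 features (15.1%), of which 186 had a p under 0.05. Summed RPKM rises (92906.5) and falls (92764.3) nearly balanced before normalization. Scaling the group means to equal sums could therefore not move the median this far. The normalization is not named, so how far it set the 47.0%, and the division of features with low p-values, cannot be told. By abundance, the median log2 RPKM ratio was -0.27 below 0.3 RPKM, -0.38 between 1 and 3 RPKM and -0.11 above 100 RPKM. The normalized log2 difference went from 0.28 below 0.3 RPKM to -0.05 between 1 and 3 RPKM and -0.13 above 100 RPKM.

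**Figure D2:**
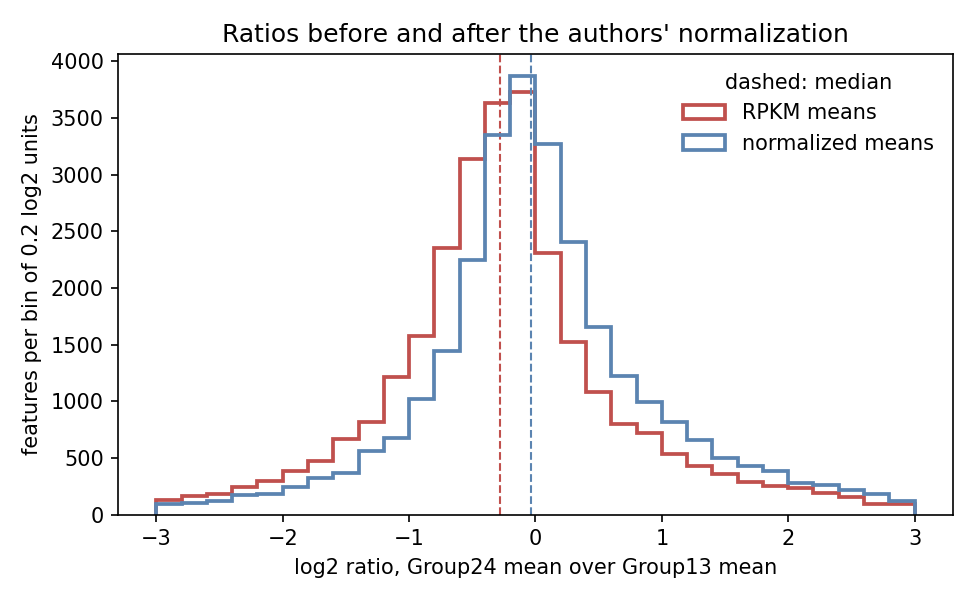
Number of tested features (vertical axis) per bin of 0.2 of the log2 ratio of the Group24 mean over the Group13 mean (horizontal axis). Ratios are the authors' deposited fold changes between RPKM means (red, 29106 features) and normalized means (blue, 29198 features). Dashed lines are medians, at -0.28 and -0.03. Ratios beyond 3 log2 units to either side lie outside the plot, 1051 for RPKM and 1071 for normalized values.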

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

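The moderated tests, the adjustment over the tested features alone, the other scales, the stricter p and the minimum levels were chosen after the data were seen. The count of 0 features at an FDR of 0.05 held with adjustment over the tested features alone. An FDR of 0.01 and a 2-fold minimum can only remove features, so their count of 0 was fixed in advance. Moderation with limma gave 429 features with every level included, 1447 with normalized values over 1 and 134 with values over 5. The cause of that spread was not tested. The 2430 features with p under 0.05 became 1099 with a 2-fold minimum, 515 at p under 0.01 and 1570 at 1 RPKM or more, each by removing features. The share of tested features higher in Group24 (47.0%) was 32.3% in RPKM, 47.7% before the log and 42.9% at 1 RPKM or more. Among features with p under 0.05 it was 38.1% in RPKM and 40.4% at 1 RPKM or more, against 45.6%. All 4 named features kept their sign on the RPKM and normalized scales, but their size moved in RPKM: the log2 ratio was 5.501 for Xelaev15017905m (6.45 on the log2 scale of normalized values), 4.74 for Xelaev15023741m (5.93), -11.17 for Xelaev15069504m (-9.82) and -9.80 for Xelaev15022482m (-9.46). The deposited test and its moderated form use the table's own pairs. With the replicate numbers of the titles as pairs, no paired analysis was possible because the library columns carry no stated link to the samples. Pitx1 RNA against water was therefore not tested in pairs. Leaving out a replicate, the edgeR and DESeq2 fits, other size factors, unique reads, pseudocounts and sums per gene were not run, for Group13 against Group24 either, because the columns per library could be matched to no sample and were left unused by choice. The gene list tests were not run because no feature could be named.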

Other observations

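The moderated tests, the exchange of labels and the tests of composition and gene length were chosen after the results were seen. With the standard errors moderated across features by limma, and Benjamini-Hochberg adjustment over 29198 features, 123 features were higher in Group24 and 306 higher in Group13, with a lowest adjusted p of 0.0138. The features Xelaev15069504m and Xelaev15022482m, both far lower in Group24, had that lowest value. With normalized values over 1, the moderated test gave 775 features higher in Group24 and 672 higher in Group13, and 385 of its calls were shared with the test over every level. With values over 5 the majority was again toward Group13, with 31 features higher in Group24 and 103 higher in Group13. Individual calls are uncertain. With the simulated spread set to the moderated spread of the real features, 62 of 192 calls were false over every level and 42 of 197 over a normalized value of 1. With the spread drawn from the fitted prior, 5 of 54 and 3 of 103 were false.

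The deposited p-values under 0.05 numbered 2430, against 1460 expected. The excess was broad: 68.7% of the tested features had a deposited p under 0.5, where chance gives 50%. Exchanging the group labels within 1 of the pairs turns each statistic into its inverse, so the features with a deposited p over 0.95 are those that would then have p under 0.05. They numbered 774. After the exchange the limma-moderated test gave 0 features under an adjusted p of 0.05 and 54 under an unadjusted 0.05, against 429 and 6430 for the deposited grouping. The exchange makes the difference and the standard error trade places, so any difference between the groups becomes spread. The 54 is far under the 1460 expected by chance, so the exchanged counts do not measure chance. The 4 libraries allow only 3 splits, too few for a share under 0.05, and the remaining split cannot be computed from these columns. An effect of the injected RNA and any other difference between the libraries of Group13 and Group24 stay open, untested.

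Most tested features were lower in Group24 in RPKM, with a median log2 ratio of -0.28. One candidate explanation is that a few abundant features took reads from the rest. The 10 features with the largest rise made up 28.9% of the summed rise in RPKM, and the 10 largest falls 8.64% of the summed fall. The largest rise was 7579 RPKM, from a Group13 mean of 3906 RPKM. Over all features, 14180 were higher in Group24 in RPKM and 27092 higher in Group13. The 10 largest rises need a shift of -0.080 in the summed RPKM of the remaining features. By abundance the median log2 RPKM ratio was -0.38 between 1 and 3 RPKM and -0.11 above 100 RPKM, so features were not shifted alike. Abundant features weigh most in a sum of RPKM, and RPKM is already divided by length. The -0.080 therefore cannot be set against the median of -0.28, and whether these few are the cause stays open. The 100 largest need -0.169 and the 1000 largest -0.30. Summed rises (92906.5 RPKM) and falls (92764.3 RPKM) nearly balance, so this shift must grow with the number set aside. It cannot decide on a broader change of composition, which stays open. A dependence on gene length as the whole cause is argued against by the shortest features, of 165 to 984 bases, whose median of -0.231 was the nearest to 0 of the 4 length classes.

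In 92 of the tested features the mean RPKM of Group24 was read as 0 from a missing fold change. The authors nevertheless gave them a log2 difference of the normalized values. Their median absolute log2 difference was 2.43, 72 differed at least 2-fold and 23 had a p under 0.05, although none differed by more than 3.57 RPKM. Without a pseudocount, a log2 value needs a normalized value above 0. If both readings hold, these differences rest on Group24 values that the normalization raised above 0. This was not checked on the group means or the values per library, which were not used. The count with Group13 read as 0 was 0.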
